A study of Homo sapiens with 4 samples.

How the data were processed

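RNA of P493-6 cells was measured in 4 samples, 2 MYC-ON and 2 MYC-OFF, with libraries made from poly(A)-selected RNA with a TruSeq RNA kit and sequenced on an Illumina HiSeq, per the labels' protocols. The deposited table gives FPKM for 60468 Ensembl genes, with 1 column per sample. STAR and Cufflinks and the build hg38 (GRCh38) are named per the submitters' processing notes. Their versions and settings and the annotation release are not given in the sources used here. Columns were assigned to samples by the description in the labels.

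Rows were matched by Ensembl ID to GENCODE release 29 on GRCh38 for coordinates, transcript length, GC content and overlaps between exons of different genes on either strand. Of all rows 93.8% matched, and of the 13953 rows with a mean FPKM of at least 1 over the 4 samples 98.7% matched. Only these 13953 rows were tested. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) on log2(FPKM + 1), with no covariate, as MYC-ON minus MYC-OFF. Calls were made at a Benjamini-Hochberg adjusted p below 0.05. Log2 differences are on the log2(FPKM + 1) scale, which understates the change of low genes. Ratios are of mean FPKM. Intervals are at the 95% level.

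FPKM hold no counts, so depth was estimated from the steps that single fragments leave in the values of genes with a transcript over 1500 nt and at most 3 exons. At these depths 71.2% to 75.4% of the values of up to 10 fragments lay within 0.15 of a whole number, against 30.0% without steps. The samples of each group differed by more than sampling noise, with chi-square per degree of freedom of 14.61 in MYC-ON and 5.35 in MYC-OFF, so none was treated as the same library deposited again, which does not show that the samples came from separate cultures. The median standard error of a log2 difference was 0.114. The limma step was tested on simulated data, with 200 of 13953 genes changed. With moderated variances it recovered 10.3% of log2 changes of 0.585, 50.6% of 1 and 92.7% of 2, and 10.9% of its calls were false. With variances drawn from the fitted prior the shares were 0.3%, 19.9% and 70.3%, and 5.7% of calls were false. In the data 9515 genes were called, far more than the 200 changed in the simulation. The adjusted threshold depends on the share of genes changed, so these figures do not give the power or error of the calls reported here.

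Before the data were examined, 37 gene lists with 834 members were fixed, of which 833 members matched the table. The 34 lists with at least 3 kept members were tested by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists. Named genes also followed a rule fixed then. It names MYC, DANCR and CDKN1A; the 5 largest called differences each way among genes with an official symbol, at least 5 FPKM in the higher group and no overlap between groups; and, per list, up to 2 called members with the largest difference and 1 of the opposite direction. Names outside it are marked as chosen after their values were seen, or complete a count of 5 or fewer. Secondary lists are given mainly as counts, so not every gene the rule names is reported here.

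Alternatives were pseudocounts of 0.1 and 0.01, filters at a mean of 0.1, of 5 and none, median centring, quantile normalization, upper-quartile scaling, a common sum without the 50 highest rows, no trend, a replicate block, limma treat against 1.5-fold, and leaving out each sample. For lists, camera with an estimated correlation and fry were added. A common sum over all kept rows and a restriction to transcripts of 200 nt or longer were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.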

Results

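P493-6 is a human B-cell line that carries an ectopic MYC gene which tetracycline switches off. RNA sequencing compared 2 libraries of cells that kept expressing MYC (MYC-ON) with 2 libraries of cells held in 0.1 µg/mL tetracycline for 48 h (MYC-OFF). The values are FPKM per gene, fragments per kilobase of transcript relative to the mapped fragments of the library. Steps in the low values put the fragments behind the FPKM at an estimated 52900000 and 42600000 for MYC-ON replicates 1 and 2, and at 45800000 and 60600000 for MYC-OFF replicates 1 and 2. At those depths 1 fragment on a 1 kb transcript is worth 0.0165 to 0.0235 FPKM. The labels do not say that the 2 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

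The first question was whether MYC itself followed the labels, and how the 2 genes named in the study's title, the long noncoding RNA DANCR and CDKN1A (the gene of p21), differed between the states. MYC and DANCR RNA were far higher in MYC-ON cells. CDKN1A RNA did not differ detectably between the 2 states. MYC (ENSG00000136997, GRCh38 chromosome 8, 127735434 to 127741434) was at 867.6 ± 80.4 FPKM (SD, n = 2) in MYC-ON and 11.4 ± 0.129 FPKM in MYC-OFF, a ratio of 76.2. The limma log2 difference was 6.13 (95% interval 5.89 to 6.37, adjusted p = 3.30e-04). DANCR (ENSG00000226950, chromosome 4, 52712404 to 52720351) was at 302.3 ± 24.2 FPKM in MYC-ON and 20.3 ± 1.77 FPKM in MYC-OFF, a ratio of 14.9. Its log2 difference was 3.83 (95% interval 3.55 to 4.12, limma adjusted p = 3.30e-04). Among 1902 long noncoding RNAs kept, DANCR ranked 5 by log2 difference and 4 by difference in FPKM. Exons of DANCR overlap those of AC104066.1 in the annotation, and without strand the reads of the 2 genes cannot be told apart. CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339, overlapping DINOL) was at 26.4 ± 5.63 FPKM in MYC-ON and 28.0 ± 1.75 FPKM in MYC-OFF. Its log2 difference was -0.09 (95% interval -0.57 to 0.38, limma adjusted p = 0.644), and without MYC-ON replicate 2 it was 0.12. p21 protein was not measured.

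**Figure D1:**
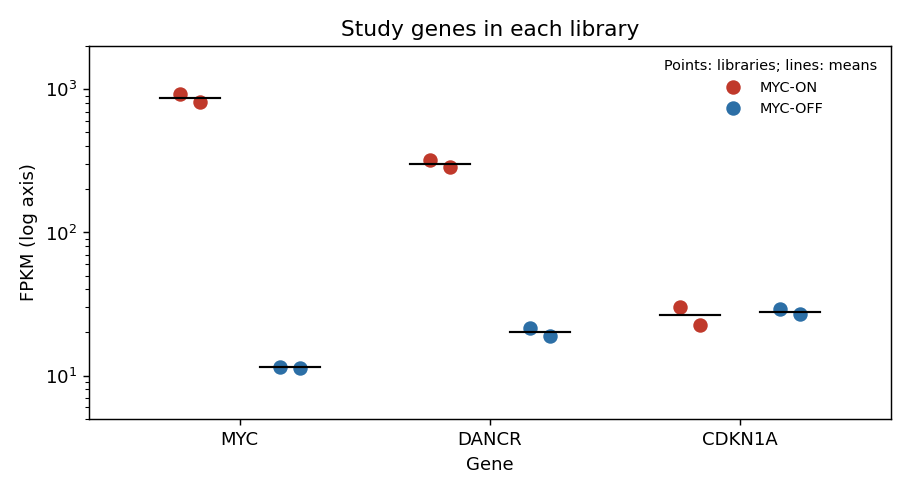
FPKM (log axis) of MYC, DANCR and CDKN1A in each of the 2 MYC-ON and 2 MYC-OFF libraries, with points for libraries and lines for group means. MYC and DANCR separate the groups, at 867.6 against 11.4 and 302.3 against 20.3 FPKM, and the CDKN1A libraries overlap.

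The second question was how the transcriptome as a whole differed between the states. MYC-ON cells had higher RNA of genes for growth, nucleotide supply and division. MYC-OFF cells had higher RNA of interferon-response, antigen-presentation and B-cell genes. Of 13953 genes kept, 9515 passed the limma threshold, 5110 higher and 4405 lower in MYC-ON. More than 2-fold differences were called for 2777 genes higher and 2161 lower. The groups did not overlap for 85.1% of genes, against 33.3% by chance for 2 against 2. Without MYC-OFF replicate 1 the genes called lower numbered 2921. FPKM are relative to each library, so a change in the RNA content per cell cannot be seen, and the balance of calls depends on the scaling. The share of calls that were higher in MYC-ON was 53.7%, against 41.5% after rescaling to a common sum and 43.2% after rescaling without the 50 highest rows. These 2 rescalings shifted the median log2 difference of all genes by -0.261 and -0.222, and upper-quartile scaling shifted it by -0.118. No list median given below changed sign under any scaling tried.

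By the rule for named genes, the largest differences higher in MYC-ON were those of SNORA84, SNORA71D, MIF, MYC and SNORA71. SNORA84 overlaps MIR3651 and SNORA71 overlaps SNHG17, which leaves their levels uncertain. The 3 small nucleolar RNAs were listed at 0 or nearly 0 FPKM in both MYC-OFF libraries, and such a 0 can be a failed estimate. The libraries were made from poly(A)-selected RNA, so values of small nucleolar RNAs and microRNAs may not measure the mature forms. Of the transcripts under 200 nt kept, 74.1% had a library under 0.001 FPKM, against 0.5% of longer ones. SLC25A6 was at 0 in all 4 libraries, but it is listed more than once and is no guide to these genes. MIF was at 300.7 and 80.0 FPKM in the MYC-ON libraries and 0.357 and 0.723 FPKM in the MYC-OFF libraries. It overlaps MIF-AS1 and AP000350.4, and its level is uncertain. The largest differences lower in MYC-ON were those of MIR320E, IFI44, IFI44L, IFI27 and XAF1. MIR320E was likewise listed at 0 in both MYC-ON libraries, with 90.0 and 180.4 FPKM in the MYC-OFF libraries. IFI44 was at 1.40 ± 0.427 FPKM in MYC-ON and 157.6 ± 0.0686 FPKM in MYC-OFF (log2 difference -6.06). Further protein-coding genes, chosen after their values were seen, were RAC3 (5.01), HPDL (4.90), CAMKV (4.86), CPNE7 (4.74) and FABP5 (4.70), higher in MYC-ON. SAMD9L (-4.55), EPSTI1 (-4.52), ITGAM (-4.47) and SLFN5 (-4.44) were lower.

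Genes for making ribosomes, nucleotides and DNA rose together in MYC-ON. All 32 ribosome biogenesis genes were higher, with a median log2 difference of 2.74, led by NOP16 (3.70) and LYAR (3.64). All 22 nucleotide synthesis genes were higher (median 2.36), led by NME1 (4.95) and PAICS (4.61). NME1 overlaps the read-through gene NME1-NME2. Of 20 genes of polyamine synthesis, one-carbon metabolism and amino acid transport, 18 were higher and 2 lower (median 2.20). SLC38A5 (4.43) and SLC7A5 (4.06) rose most, and SLC38A2 fell (-0.96). All 28 DNA replication genes were higher (median 2.05), with MCM4 at 3.15 and GINS2 at 3.06. All 24 mitosis genes were higher (median 1.91), with BUB1B at 2.89 and BIRC5 at 2.81. Adjusted over the list alone, the counts of these 5 lists were the same. By camera with its preset correlation, ribosome biogenesis had an adjusted p = 4.73e-12 and mitosis 3.00e-09. With an estimated correlation each of these 5 lists had a camera adjusted p = 0.131, and 0 of the 34 lists tested passed, against 26 with the preset value and 34 by fry. The estimate was below the preset value for mitosis (-0.043), nucleotide synthesis (-0.03) and the polyamine, one-carbon and amino acid transport list (-0.017). It was above for ribosome biogenesis (0.032) and DNA replication (0.03). A higher adjusted p with an estimated correlation is therefore not by itself a sign of correlated genes. That form of camera rests on the few residual degrees of freedom of 4 samples, and the preset form on the number of genes. Failing it therefore does not decide whether a list changed. Unlike camera, fry tests a list against no change and not against the other genes, so its count is not comparable.

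Genes of the G1 phase went both ways, and the p53 targets called were lower apart from AEN. The list of cyclins, CDKs and CDK inhibitors also holds CDC25A and genes of the E2F and RB families. Of its 17 kept genes, 10 were higher, 5 lower and 2 not called, the last being CDKN1A and CCND2 (median 0.74, camera adjusted p = 0.398). It mixes cyclins and CDKs with CDK inhibitors, so 1 direction for the whole list says little. The 5 lower were CDKN1B, CDKN2D, CCND3, RB1 and RBL2. The CDK inhibitor CDKN2A (1.29), chosen after its values were seen, was higher. CDC25A (3.13) and CDK4 (2.57) were higher, and CDKN2D (-1.97) was lower. Of 23 kept p53 targets, 1 was higher, 13 lower and 9 not called, with a median of -0.43 and a camera adjusted p = 0.00925, or adjusted p = 0.203 with an estimated correlation. BTG2 (-1.95) and TP53INP1 (-1.85) were lower and AEN (1.19) was higher. CDKN1A was among the 9 not called, as were MDM2 (-0.09), BAX (-0.26) and BBC3 (0.46), chosen after their values were seen. BTG2 and SESN1 are also members of the quiescence and FOXO-responsive list, so these lists are not independent. Of the p53 targets, 7 were lower without MYC-OFF replicate 1 and 6 without MYC-OFF replicate 2, while 2 were higher without MYC-ON replicate 1 and 4 without MYC-ON replicate 2. Adjusted over the list alone, both lists had the same counts. In the MYC-MAX network, 4 of 10 kept genes were higher, 4 lower and 2 not called, and 5 were lower adjusted over the list alone. Its median was -0.33 and its mean 0.54, and camera put it down (adjusted p = 0.788). MYC itself (6.13), which tetracycline switches off, is a member, counts among the 4 higher and raises the mean. Without MYC-OFF replicate 1, and likewise without replicate 2, 2 were higher and 1 lower, and each of the 5 other scalings gave 2 higher and 4 to 6 lower. MXI1 rose (1.87) and MXD4 fell (-0.94), the latter not called without MYC-OFF replicate 1 (-0.98) or 2 (-0.90).

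Calls differed between the snoRNA host genes and the other long noncoding RNAs, though no test compared the lists. Of 24 snoRNA host genes, 23 were higher in MYC-ON and 0 lower (median 1.72), with SNHG4 (4.26) and DANCR (3.83) the largest. SNHG4 overlaps MATR3 and SIL1, so its level is uncertain. After rescaling to a common sum, 21 were higher and 1 lower. The camera adjusted p was 1.44e-07, or adjusted p = 0.131 with an estimated correlation. Of 11 other long noncoding RNAs kept, 2 were higher, 6 lower and 3 not called (median -0.70, camera adjusted p = 0.0975). MIR17HG (3.28) and OIP5-AS1 (0.92) were the 2 higher, and MIR22HG (-2.65) fell most. Both lists had the same counts adjusted over the list alone. Of all long noncoding RNAs kept, 450 were higher and 674 lower, against 4423 and 3469 of 10748 protein-coding genes.

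Genes of B-cell identity, antigen presentation and quiescence fell in MYC-ON. All 19 kept B-cell identity genes were lower (median -1.50), with CD72 at -3.51 and CD24 at -2.80, and the camera adjusted p = 7.05e-08 became adjusted p = 0.203 with an estimated correlation. All 12 MHC class II genes were lower (median -2.39), with HLA-DOB at -2.71 and HLA-DPB1 at -2.70, levels that reads shared between related HLA genes leave uncertain, and the camera adjusted p = 8.17e-07 became adjusted p = 0.334 with an estimated correlation. Of 21 kept NF-kB and EBV-responsive genes, 18 were lower and 1 higher (median -1.47; camera adjusted p = 8.99e-06, or adjusted p = 0.251 with an estimated correlation). CCL22 (-3.17) and CCL17 (-2.94) fell, and BATF (1.38) rose. Of 26 lysosome and autophagy genes, 18 were lower and 2 higher (median -0.79; camera adjusted p = 1.16e-04, or adjusted p = 0.359 with an estimated correlation). Without MYC-OFF replicate 1, and likewise without replicate 2, 11 were lower and 0 higher. TPP1 (-2.22) and CTSZ (-2.03) fell. GAA (1.96) rose, but not past the threshold without either MYC-OFF replicate 1 (1.98) or 2 (1.95). Of 16 kept quiescence and FOXO-responsive genes, 14 were lower and 1 higher (median -1.29; camera adjusted p = 4.00e-05, or adjusted p = 0.15 with an estimated correlation). SATB1 (-3.25) and TXNIP (-3.22) fell, and IL7R (2.36) rose. Adjusted over the list alone, the counts of these 5 lists were the same.

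**Figure D2:**
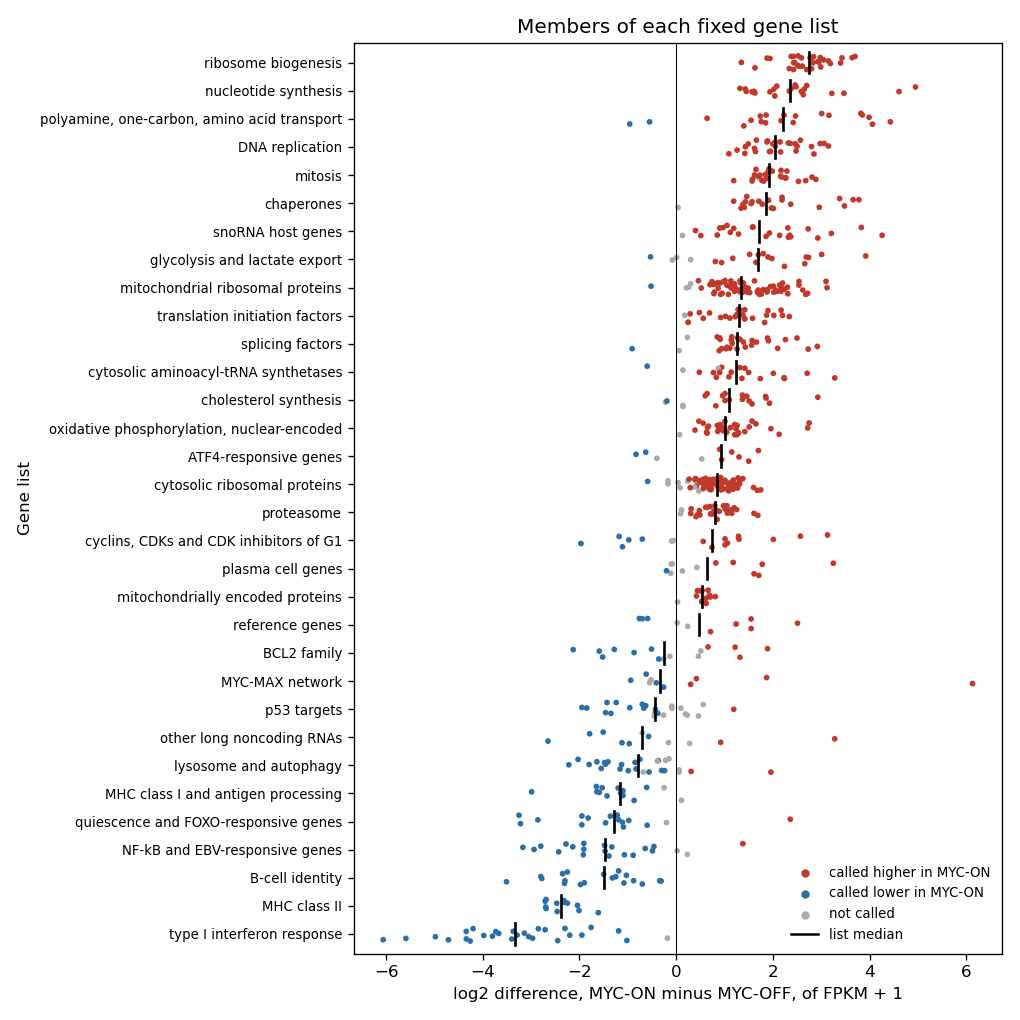
Log2 difference between MYC-ON and MYC-OFF of FPKM + 1 (x axis) for each kept member of the fixed primary and secondary gene lists, without the markers of other cell types (y axis), coloured by limma call, with vertical lines for list medians. Medians of the lists plotted run from 2.74 for ribosome biogenesis to -3.33 for the type I interferon response.

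Lists fixed as secondary are given as counts, with the same counts adjusted over the list alone unless stated. Cytosolic ribosomal proteins had 67 of 75 higher and 1 lower (68 higher over the list alone), mitochondrial ribosomal proteins 68 of 72 higher and 1 lower (70 higher over the list alone), and nuclear-encoded oxidative phosphorylation 33 of 34 higher. Of the cytosolic ribosomal proteins, 40 were higher without MYC-OFF replicate 1 and 39 without MYC-OFF replicate 2, both with 0 lower, 63 were higher and 2 lower without MYC-ON replicate 1, and 39 were higher and 8 lower under quantile normalization. Of the mitochondrial ribosomal proteins, 2 were lower without MYC-ON replicate 1 and 0 without MYC-OFF replicate 1. Mitochondrially encoded proteins had 12 of 13 higher, but 1 without MYC-OFF replicate 1 and 3 without MYC-OFF replicate 2. They had 2 higher and 1 lower under quantile normalization, and 7 higher and 1 lower after rescaling to a common sum. Glycolysis and lactate export had 15 of 19 higher and 1 lower, and cytosolic aminoacyl-tRNA synthetases 17 of 20 higher and 1 lower. Translation initiation factors had 24 of 26 higher (25 over the list alone), chaperones 21 of 22, and the proteasome 29 of 31. Splicing factors had 26 of 29 higher and 1 lower (27 higher over the list alone), and cholesterol synthesis 17 of 21 higher and 1 lower. Several more lists had fewer genes called without MYC-OFF replicate 1 or 2, with similar medians. These medians were 0.81 and 0.80 for the proteasome and 1.06 and 0.97 for nuclear-encoded oxidative phosphorylation. They were 1.40 and 1.32 for mitochondrial ribosomal proteins and 1.19 and 1.11 for cholesterol synthesis. Over all 4 samples the medians in this order were 0.80, 1.02, 1.35 and 1.10. The 1 lower gene of glycolysis was not called without MYC-ON replicate 2 or either MYC-OFF replicate. That of cholesterol synthesis was not called without either MYC-OFF replicate, and 2 were lower without MYC-ON replicate 1. These 11 lists passed camera, with adjusted p from 0.131 to 0.477 with an estimated correlation. The type I interferon response had 27 of 28 lower, all but MX2 (median -3.33; camera adjusted p = 1.43e-12, or adjusted p = 0.131 with an estimated correlation). MHC class I and antigen processing had 12 of 14 lower and 0 higher, or 1 higher without MYC-ON replicate 2 (camera adjusted p = 6.89e-05, or adjusted p = 0.359 with an estimated correlation). ATF4-responsive genes had 6 of 10 higher and 2 lower, the BCL2 family 4 of 15 higher and 7 lower, and plasma cell genes 6 of 12 higher and 1 lower (0 lower over the list alone), and none of these 3 passed camera. Without MYC-OFF replicate 1, and likewise without replicate 2, the ATF4-responsive genes had 4 higher and 0 lower and the BCL2 family 2 higher and 3 lower. Without MYC-ON replicate 2 the ATF4-responsive genes had 7 higher and 1 lower. The plasma cell genes passed camera with its preset correlation without MYC-OFF replicate 1, while over all 4 samples camera with an estimated correlation gave an adjusted p = 0.359. Their 1 lower gene was not called without any 1 of the 4 samples. Reference genes had 5 of 10 higher and 3 lower and did not pass camera.

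Markers of other cell types were mostly near 0. The 3 kept myeloid markers, ITGAM (-4.47), CD68 (-3.72) and LYZ, were lower in MYC-ON (camera adjusted p = 0.00572, or adjusted p = 0.331 with an estimated correlation). Of 5 kept T-cell markers, 3 were lower, including CD2 (-2.28) and CD3G (-0.93), and 2 were not called (camera adjusted p = 0.0975). PRF1 (-0.89) was lower among 2 kept NK-cell markers, and NKG7, the other, was called higher without MYC-OFF replicate 1. Both kept fibroblast markers, PDGFRB (-1.67) and COL1A1 (-0.86), were lower, and EPCAM (1.72), the 1 kept epithelial marker, was higher. The counts of these lists were the same adjusted over the list alone.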

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

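The restriction to transcripts of 200 nt or longer and the common sum over all kept rows were chosen only after the data were seen. MYC and DANCR stayed higher in MYC-ON and past the threshold in all 18 alternatives, with log2 differences of 5.83 to 6.25 and 3.53 to 3.92. CDKN1A passed in 0 of 18, with log2 differences of -0.39 to 0.12 and limma adjusted p of 0.0794 to 1. Leaving out 1 replicate moved it between -0.31 and 0.12, and the sign changed without MYC-ON replicate 2, a fit with fewer samples.

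Tested against a 1.5-fold change, 5117 genes passed, 2861 higher and 2256 lower in MYC-ON, since that test asks for more. Leaving out 1 replicate gave 2921 to 4219 genes lower. Each lone sample is then assumed to vary like the other group. Quantile normalization gave 4 genes called in both fits with opposite signs. Of 103 other named genes, 85 kept direction and call in every alternative that tested them, 18 lost the call in at least 1, and 0 changed sign. The filter at a mean FPKM of 5 did not test 10 of them, and the restriction to 200 nt or longer did not test 4.

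With an estimated correlation, camera called 0 lists against 26. The estimate was below the preset value for mitosis (-0.043), nucleotide synthesis (-0.03) and cytosolic aminoacyl-tRNA synthetases (-0.022). Their camera adjusted p still rose to 0.131, which argues against a higher correlation between genes as the cause for these lists. Other lists, such as MHC class II (0.679), had estimates above the preset value. Camera with an estimated correlation also rests on the few residual degrees of freedom of 4 samples, which the preset form does not. How much each of these matters was not tested. For the MYC-MAX network, not called by camera, the direction given by the test changed in 3 settings. These were fry (median -0.33, mean above 0), no filter (median -0.13) and a mean FPKM of at least 5 (median 0.02). With no filter the median itself stayed below 0, and the cause was not tested. Mitochondrially encoded proteins lost the call under quantile normalization, with a median of 0.10, and myeloid markers with no filter (-1.71). The other long noncoding RNAs, plasma cell genes and T-cell markers gained it with the filter at 0.1 and with no filter, and plasma cell genes also without MYC-OFF replicate 1.

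The replicate numbers share no stated origin. Same-numbered samples deviated with a correlation of -0.027 across genes. A fit with the replicate block called 9141 genes, including 93.6% of those called without it. The treat test applies to genes, and it was not run for lists.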

Other observations

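The tests of scaling, of monocytes and granulocytes, of interferon genes and of short transcripts were chosen only after the results were seen, while those of length or GC content and of library depth were set down before their values were computed. The lists for ribosome biogenesis, nucleotide synthesis, DNA replication and mitosis were higher in MYC-ON. Over 5 scalings the lowest of their medians was 1.61, which argues against scaling as the whole cause. After a loess fit on transcript length and GC content, which moved genes by a median of 0.14, the lowest was 1.76. Between the 2 MYC-OFF libraries, at 45800000 and 60600000 fragments, the members differed by a median of -0.005. FPKM are already relative to the fragments of the library, so a small difference was likely in advance and does not decide whether depth mattered. A candidate explanation that stays open is the change in MYC, but tetracycline was given to both MYC-OFF samples and to no MYC-ON sample, so its own effect cannot be separated.

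The type I interferon response, MHC class II and B-cell identity lists were lower in MYC-ON, with a highest median of -1.57 over 5 scalings. LYZ was at 61.96 and 66.58 FPKM, ITGAM at 126.8 and 121.9, and CD68 at 86.59 and 80.37 in the MYC-OFF libraries, so cells of another type were weighed. Such cells would dilute RNA found only in B cells, but the B-cell identity list was lower in MYC-ON, not in MYC-OFF (median -1.50). That argues against monocytes and granulocytes only for members that such cells do not express, which was not checked. It is also the pattern itself, known before the rule was set, so it adds no separate evidence. For the other lists, the mean MYC-OFF FPKM of CD14, CSF1R and FCGR3A was at most 0.0263% of that of LYZ, with CD14 at 0.182 and 0.1233 FPKM in MYC-ON against 0 and 0.01038 in MYC-OFF, which argues against monocytes. Granulocytes cannot be told apart for the interferon and MHC class II genes, because 4 of their markers, S100A8, S100A9, MPO and ELANE, are listed at 0 in all 4 libraries, which can be a failed estimate, and ITGAX, looked at afterwards, was at 15.1 and 16.22 FPKM in MYC-OFF. A hypothesis is that interferon genes were transcribed in MYC-OFF: the summed FPKM of 17 type I interferon genes was 0.565 and 0.605 in MYC-OFF against 0.0883 and 0.107 in MYC-ON, a lowest ratio of 5.31, or 1.62 without IFNA2, from values near the floor that may not reflect secreted interferon.

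Transcripts under 200 nt made up 4.1% of the genes kept and 49 of the 100 largest differences. At matched mean FPKM, samples of 1 group differed 15.1 times as much for these as for longer transcripts, as imprecise FPKM of short transcripts would give. Of 164 snoRNAs kept, 46 were called higher and 5 lower in MYC-ON, with a median log2 difference of 1.40. Imprecision alone gives no such direction. Of the short ones 74.1% had a library under 0.001 FPKM, against 0.5% of the longer ones. SNORA26 (chromosome 4, 52713249 to 52713370), chosen after its values were seen, lies between the start and end of DANCR without overlapping its exons and was at 203.4 and 104.7 FPKM in MYC-ON and 41.97 and 21.04 in MYC-OFF. No biological explanation was tested.

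The 21 snoRNA host genes that are long noncoding RNAs had a median log2 difference of 1.93, against -0.20 for the 1881 other long noncoding RNAs kept. Among reference genes HPRT1 (2.51) and PPIA (1.55) were higher in MYC-ON. SLC16A1 (3.92) and LDHA (3.01) were higher, while SLC2A1 (-0.53) was lower but not called without MYC-ON replicate 2 (-0.43) or without MYC-OFF replicate 1 (-0.45) or 2 (-0.61). Among chaperones FKBP4 (3.78) and TRAP1 (3.66) led, and among plasma cell genes FKBP11 (3.25). In the BCL2 family BCL2L11 (1.89) was higher and HRK (-2.13) lower.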
